A study of Mus musculus with 4 samples.

How the data were processed

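Retina and choroid of wild-type mice, 6 to 8 weeks or over 18 months old, were profiled without lesions or 3 days after laser photocoagulation (532 nm, 200 mW, 0.15 s, 100 µm spot), 1 library per group. Per the labels' protocols, choroid-sclera and retina were digested separately with papain, passed through a 40 µm mesh, rods were depleted from the retina with antibodies against CD73, and the suspensions were mixed at 200 cells per µL for 10x Genomics Chromium. The deposited values are raw counts, UMIs per gene and cell in 1 matrix of 24783 genes and 36701 cells, whose column prefixes gave 4 libraries and left 0 columns unmapped. The prefix y was read as young and e as aged, since e was the only other code. Per the submitters' processing notes Cell Ranger and Seurat 4.1.1 were used on mm10. The Cell Ranger version and the annotation are not given in the sources used here. The values show a cell filter already applied: the lowest UMIs per cell were 500, 507, 504 and 502 and the lowest genes per cell 201, 201, 203 and 201 in young control, young CNV, aged control and aged CNV, and mitochondrial UMIs stayed under 20%. Total UMIs per library ranged from 50848238 to 111908519. Of cells with at least 5000 UMIs, 85.0%, 85.0%, 88.9% and 89.8% had UMIs of Y-linked genes and none of Xist, and at most 0.0490% Xist alone, so no library stood apart by sex.

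Cells with at least 200 genes and at most 25% mitochondrial UMIs were kept, which removed 0 cells. Scrublet was run per library in scanpy 1.11.5. Its automatic threshold called 0 cells in young control, so a fixed score of 0.2 was set after the scores were seen, which removed 303, 290, 246 and 272 cells and left 35590. All libraries were clustered together without integration: 2000 variable genes, 40 principal components, 20 neighbours, a shared-neighbour graph pruned at 0.0667 and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 1). Leukocyte clusters, those with Ptprc in at least 30% of cells, were clustered again, because NK cells had merged with T cells and neutrophils with mast cells. This step was not part of the plan. It gave 65 clusters, 25 of them of leukocytes. A cluster was named after the class whose fixed markers had the highest mean log2 fold over the other clusters (5 CPM added), given at least 3 markers with a log2 fold of at least 1 and 20 CPM or more and, among its 10 leading genes of at least 100 CPM, no more markers of another class than of its own. Clusters whose 2 best scores lay within 0.5 were left unnamed, a margin added after the cluster table was seen, and 2 exploratory clusterings preceded the final one. The naming thresholds were also set after the data were seen. Clustering and tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0, figures matplotlib 3.10.9, and scaling factors R 4.3.3 with edgeR 4.0.16.

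The comparisons, marker and gene lists, ligand and receptor pairs, rule for named genes and alternative settings were chosen before the data were examined. Shares are given with exact Clopper-Pearson 95% intervals over all cells and over leukocytes other than microglia-like cells, where unnamed leukocyte clusters count in the denominator. UMIs were summed per class and library, and CPM carry exact Poisson intervals and ratios exact conditional binomial intervals. Against a library with 0 UMIs a fold is computed from 3 counts per library and written as at least, and with both libraries at or under 3 counts none is given. Genes needed 20 UMIs over the 2 libraries of a contrast. Per contrast and class of at least 50 cells in both libraries (20 for NK-like and neutrophil-like cells), the rule named the 3 genes per side with the largest log2 ratio by the interval bound nearest 0. Their CPM had to reach 0.1 of that in the class with the highest CPM in the same library, a guard against free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models were left out. This gave 300 values, of which 36 fell under 0.1 when unnamed clusters were also counted as sources, an alternative added later. The text gives up to 2 genes per side, in the order of the rule and leaving out those 36 unless it says so, for the classes most relevant to the eye and to NK cells and neutrophils, a choice made after the values were seen. Some genes and pairs are not reported here. The free RNA rule was itself corrected to its wording after a preliminary gene table.

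For each of 27 gene lists, class and contrast with at least 5 measured members, 1058 in all, the median log2 ratio was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, and the random range is their central 95%. Which class each list is described in, and the 10 classes over which counts of classes run, were chosen after the values were seen, and counts over the other classes were added later. Up to 4 members are named per list by size of ratio. For named genes of the laser contrasts the 2 log2 ratios are set side by side. With 1 library per group no group has replicates and no test across animals was run. An additive model of age and laser was not fitted, as its only residual would be the difference between the laser effects. The steps were tested on simulated data for 13503 genes of endothelial-like cells, where 95.7% of intervals held the true ratio, 100% of genes with a true log2 ratio of 1 or 2 were recovered, and 95 of 100 unchanged lists fell within the random range. The simulated counts were Poisson draws, which the intervals assume, and the unchanged lists were randomly picked genes. The simulation thus checks the calculation only. It cannot show how intervals or percentiles behave with spread between cells or animals, or with co-expressed genes.

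Alternatives set beforehand were resolutions 0.5 and 2.0, each library clustered alone, cells picked by their own UMIs, a stricter cell filter (500 genes, 10% mitochondrial UMIs), doublets kept, a leukocyte denominator, trimmed-mean and median-of-ratios scaling, cells thinned to 1000 UMIs with shallower cells left out, minimums of 1, 5 and 100 UMIs, and 20 bins. Added after the data were seen were a denominator without rod-like cells, naming without the score margin, unnamed clusters as sources of free RNA, and counts over every class with a value. Thinning left out 16.8%, 4.32%, 3.22% and 3.33% of cells of young control, young CNV, aged control and aged CNV. Sequence reads were not used here.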

Results

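Retina and choroid of wild-type mice were measured by droplet single-cell RNA sequencing in 4 libraries, 1 each from young mice without lesions, young mice 3 days after laser burns that induce choroidal neovascularisation (CNV), aged mice without lesions and aged mice 3 days after laser burns. Young mice were 6 to 8 weeks old and aged mice over 18 months. The series asks which immune cells enter the tissue, what features natural killer (NK) cells have, and how NK cells and neutrophils interact. The young control library held 11427 cells and 68966431 UMIs, the young CNV library 10867 cells and 111908519 UMIs, the aged control library 6676 cells and 50848238 UMIs, and the aged CNV library 7731 cells and 69011793 UMIs. Median UMIs per cell were 2593, 7223, 6428 and 6875 in the same order. After removal of predicted doublets 11124, 10577, 6430 and 7459 cells remained. There were no replicates, so no difference was tested between animals, and all intervals are 95% intervals that cover counting error only. Classes are called X-like because they were named from marker genes of clusters, and rods had been depleted and retina and choroid suspensions mixed, which sets shares of all cells. Folds are ratios of CPM, UMIs scaled to the class's total, within a class, with the interval in parentheses, and a fold marked "at least" takes 3 counts for a library with 0 UMIs, and the limit of its exact interval lies lower. List values are median log2 ratios with their percentile among 10000 random lists matched on expression, as a description of these libraries. Members of lists named as examples have intervals that exclude 0. Counts of classes cover 10 classes where each had a value, namely RPE-like, rod-like, cone-like, Müller-glia-like, endothelial-like, pericyte/smooth-muscle-like, fibroblast-like, macrophage/monocyte-like, neutrophil-like and T-like cells. Counts over every class with a value, where added, are marked as such.

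Free rod RNA differed strongly between the libraries. The rod free RNA list was below the random range in 7 of 8 classes in the young laser comparison, 7 of 10 in the aged laser comparison and 8 of 8 between controls, while between CNV libraries it was below in 6 and above in 2 of 8. Rod-like cells, where these genes are the cells' own RNA, are among the classes counted. Over every class it was below in 13 of 14, 7 of 13, 10 of 10 and 9 of 12 in the same order, and above in 0, 2, 0 and 3. With cells thinned to 1000 UMIs it was below in 7 of 8, 3 of 6, 8 of 8 and 3 of 7 of the 10 classes with a value, and above in 1, 0, 0 and 0. RNA of RPE genes differed outside RPE-like cells too: the visual cycle list was above the random range in 6 of 9 other classes between controls, such as 1.72 at percentile 100 in pericyte/smooth-muscle-like and 0.83 at percentile 99.99 in endothelial-like cells, and below in bipolar-like cells. Scaling by trimmed means moved the median of all genes by -0.363 to 0.252 log2, and median-of-ratios scaling by -0.367 to 0.255, against total-UMI scaling over 35 pairs of these classes and contrast, of which 14 moved by over 0.1 under each. None of the 210 values of genes that the rule named in these classes reversed under either scaling. Directions below refer to total-UMI scaling.

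The question of immune cell entry was addressed with shares of cells. NK-like cells were rare in every library, with 6, 14, 7 and 4 cells in young control, young CNV, aged control and aged CNV. Their share of all cells was 0.0539% (0.0198 to 0.117), 0.132% (0.0724 to 0.222), 0.109% (0.0438 to 0.224) and 0.0536% (0.0146 to 0.137) in that order. The CNV to control ratio was 2.45 (0.886 to 7.79) in young and 0.493 (0.106 to 1.94) in aged mice, and the aged to young ratio 2.02 (0.581 to 7.27) in controls and 0.405 (0.0971 to 1.29) after laser, so every interval over all cells spanned 1. Among leukocytes other than microglia-like cells the laser ratio was 0.497 (0.179 to 1.58) in young and 0.243 (0.0521 to 0.955) in aged mice, the latter excluding 1. With cells picked by their own UMIs the laser ratio was 2.55 (1.007 to 7.29) in young and 0.739 (0.205 to 2.57) in aged mice, the former just excluding 1. A difference in NK-like share of all cells was thus not settled at this depth.

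Neutrophil-like cells were more frequent in both aged libraries and after laser. They made up 0.0270% (0.00556 to 0.0788) of cells in young control (3 cells), 0.180% (0.108 to 0.280) in young CNV (19 cells), 0.436% (0.290 to 0.629) in aged control (28 cells) and 2.76% (2.40 to 3.16) in aged CNV (206 cells). The laser ratio was 6.66 (1.96 to 35.1) in young and 6.34 (4.26 to 9.78) in aged mice, and the aged to young ratio 16.2 (4.99 to 83.0) without and 15.4 (9.60 to 26.1) with lesions. Among leukocytes other than microglia-like cells the aged ratios stayed above 1, at 3.13 (2.10 to 4.82) for laser, 5.94 (1.84 to 30.6) between controls and 13.8 (8.60 to 23.4) between CNV libraries, whereas the young laser ratio was 1.35 (0.397 to 7.11). With cells picked by their own UMIs the shares were 0.378% in young CNV and 1.998% in aged CNV, and the laser ratio was 10.5 (3.80 to 40.5) in young and 3.47 (2.41 to 5.12) in aged mice, so the near equality of the laser ratios does not hold under that choice. The 4 libraries held 4, 40, 37 and 149 such cells, and 107 of the 206 neutrophil-like cells of aged CNV were among them.

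**Figure D1:**
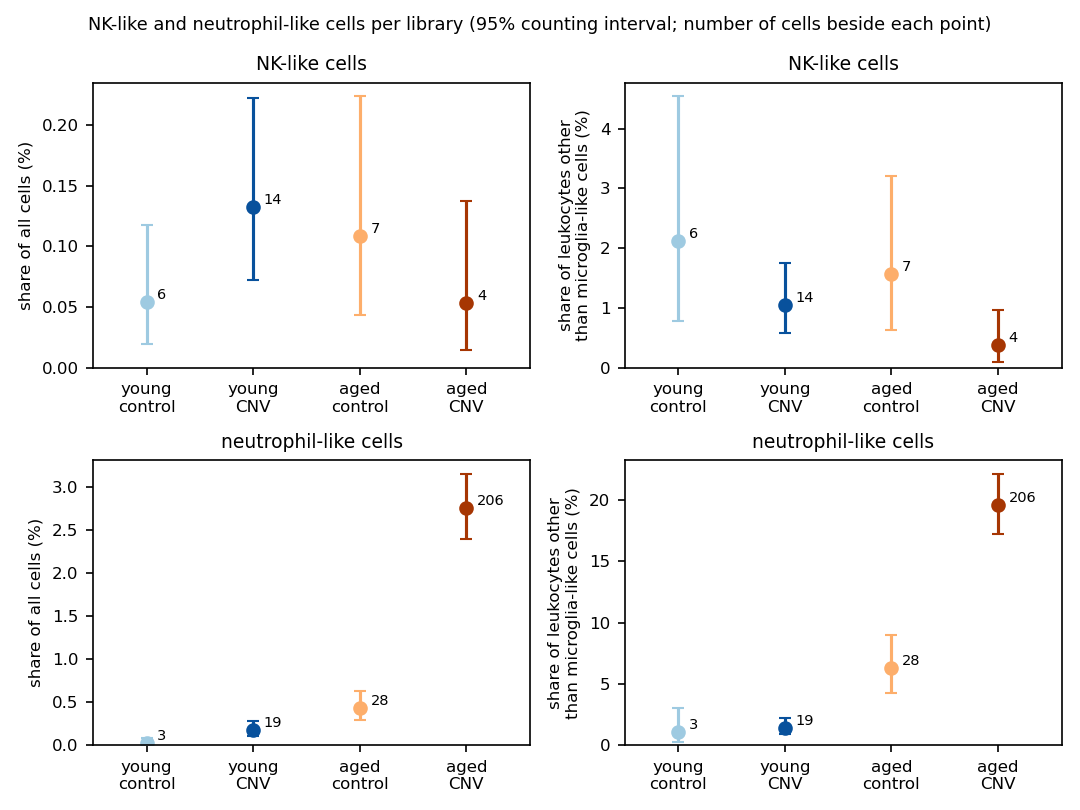
Share of NK-like and neutrophil-like cells in the 4 libraries, as percent of all cells and of leukocytes other than microglia-like cells (y axes), with points for the 1 library per group, bars for 95% Clopper-Pearson intervals and the number of cells beside each point. Neutrophil-like cells reach 2.76% of all cells in aged CNV against 0.180% in young CNV, while NK-like cells stay between 0.0536% and 0.132%.

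Other leukocytes also differed. Leukocytes other than microglia-like cells were 2.55% of cells in young control, 12.6% in young CNV, 6.94% in aged control and 14.1% in aged CNV, a laser ratio of 4.94 (4.34 to 5.64) in young and 2.03 (1.82 to 2.27) in aged mice. Macrophage/monocyte-like cells, which take up debris and present antigen, were higher after laser by a ratio of 6.19 (5.13 to 7.52) in young and 2.58 (2.10 to 3.18) in aged mice. T-like cells were 0.225%, 0.492%, 2.43% and 2.33% of cells, with a laser ratio of 2.19 (1.33 to 3.68) in young and 0.962 (0.770 to 1.20) in aged mice and an aged to young ratio of 10.8 (7.05 to 17.2) in controls. With rod-like cells left out of the denominator every share ratio is multiplied by 0.648 in the young laser comparison, 0.901 in the aged one, 0.587 between controls and 0.817 between CNV libraries. This left young laser ratios of 3.20 (2.82 to 3.65) for these leukocytes and 1.42 (0.864 to 2.39) for T-like cells, the latter spanning 1. Dendritic-like cells had laser ratios of 6.22 (3.94 to 10.3) and 2.47 (1.498 to 4.21). The largest cluster of macrophage/monocyte-like cells differed between the libraries: a cluster led by Cd163 and F13a1 in young control, by Ms4a4c and Fcgr1 in young CNV, by Adgre4 and Chil3 in aged control and by Cxcl13 and Cd209d in aged CNV. Clusters left unnamed held 3.29%, 4.76%, 2.97% and 6.48% of cells, and 29.6%, 24.96%, 15.2% and 16.3% of the leukocytes.

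Tissue classes differed too. RPE-like cells were 4.31%, 3.16%, 16.0% and 4.30% of cells, with laser ratios of 0.733 (0.636 to 0.845) in young and 0.269 (0.236 to 0.305) in aged mice. Rod-like cells, the class that was depleted, were 52.3%, 26.5%, 18.8% and 9.93%. Fibroblast-like cells were higher after laser by 1.87 (1.77 to 1.98) in young and 1.10 (1.02 to 1.19) in aged mice, and endothelial-like cells by 1.51 (1.36 to 1.68) in young mice, with 0.953 (0.833 to 1.09) in aged mice. Cone-like cells were lower after laser in aged mice, 0.589 (0.529 to 0.656), with 0.836 (0.692 to 1.01) in young mice. With rod-like cells left out of the denominator the endothelial-like ratio was 0.981 (0.882 to 1.09) in young and 0.859 (0.751 to 0.983) in aged mice, the fibroblast-like ratio 0.991 (0.917 to 1.07) in aged mice and the cone-like ratio 0.542 (0.449 to 0.655) in young mice, so these calls depend on the rod-like cells.

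**Figure D2:**
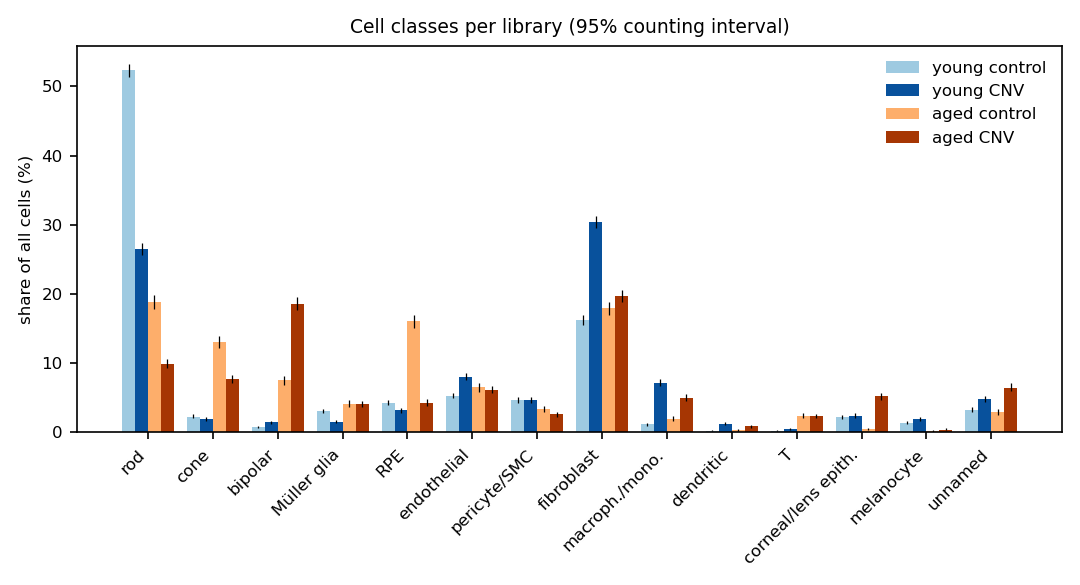
Share of each cell class as percent of all cells (y axis) in the 4 libraries (bar colours), with error bars for 95% Clopper-Pearson intervals. Rod-like cells stand at 52.3% in young control and 9.93% in aged CNV, and RPE-like cells at 16.0% in aged control against 4.30% in aged CNV.

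Features of NK-like cells were read as CPM over 44201, 89982, 44548 and 33561 UMIs of young control, young CNV, aged control and aged CNV. Prf1, the pore-forming perforin, was at 407 (241 to 644) in young control and 2414 (1917 to 3000) in aged CNV, with 967 and 1145 between them. Gzma, a granule protease, was at 8484, 8991, 4243 and 7360. Both genes lead the NK-like cluster and helped to define it. The chemokine Ccl4 was higher in young CNV, at 2467 (2153 to 2814), than in the other libraries, which gave 928, 606 and 1132. Xcl1, which attracts cross-presenting dendritic cells, stood at 1045 (844 to 1278) in young CNV and at 158, 494 and 89.4 in the other libraries. Ifng, the gene of interferon gamma, was at 385 (224 to 616), 233 (145 to 357), 112 (36.4 to 262) and 238 (103 to 469.7), overlapping intervals on 5 to 21 UMIs. Tgfb1 had 0 UMIs in young control and 122, 427 and 179 CPM in the others. With 4 to 14 cells per library no gene list was computed in NK-like cells.

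Fixed ligand and receptor pairs were read side by side for NK-like and neutrophil-like cells. In neutrophil-like cells Ifngr1, which binds interferon gamma, was at 229, 254, 217 and 148 CPM, and Ifngr2 at 152, 160.4, 242 and 112, beside the Ifng levels of NK-like cells given above. Ccl5, a chemokine of NK and T cells, was the highest ligand of NK-like cells among those pairs, at 15540, 8746, 6689 and 11530, and its receptor Ccr1 stood at 838, 321, 442 and 254 in neutrophil-like cells. Fasl was at 204, 256, 269 and 209, and Fas at 305, 147, 142 and 44.6. Tgfb1 of NK-like cells faced Tgfbr1 at 0, 508, 66.7 and 419 and Tgfbr2 at 305, 120.3, 192 and 102 in neutrophil-like cells. In the other direction Il15, which sustains NK cells, was at 609.6, 40.1, 475 and 103 in neutrophil-like cells, and Il2rb at 634, 1078, 1324 and 1132 in NK-like cells. Icam1 was at 0, 602 (439 to 805), 33.3 and 268 (229.5 to 311) in neutrophil-like cells, facing Itgal at 475, 489, 404 and 417. H2-T23 was at 76.2, 201, 83.3 and 57.0, facing the inhibitory receptor gene Klrc1 at 249, 233, 516 and 179. Csf2, Cxcr2 and Il1r1 had 0 UMIs in NK-like cells, which limits each to 3 counts per library. The young control values of neutrophil-like cells rest on 3 cells.

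Further pairs are given for young CNV and aged CNV. From NK-like to neutrophil-like cells, Ccl3 was at 278 and 626 and Itgb2, the shared chain of leukocyte integrins, at 333 and 238. The receptors Csf2ra, at 147 and 98.5, Csf2rb, at 201 and 429, and Tnfrsf1a, at 174 and 103, faced ligands with too few UMIs in NK-like cells. From neutrophil-like to NK-like cells, Ccl3 was at 4037 and 2187 and Ccl4 at 4197 and 2156. Tnf was at 962 and 603 facing Tnfrsf1b at 145 and 328. H2-D1 was at 1149 and 768 in neutrophil-like cells and Klra8 at 333 and 0 in NK-like cells. Klrd1, which pairs with Klrc1, stood at 1167 and 477. Clec2d was at 66.8 and 66.2 in neutrophil-like cells and Klrb1c at 1089 and 983 in NK-like cells. H2-D1 with Klra8 and Clec2d with Klrb1c were among the fixed pairs. Neither is taken here as an established ligand and its receptor. The interleukin 18 receptor genes Il18r1 and Il18rap were at 567 and 478 in young CNV and at 0 and 894 in aged CNV. Il1b, at 5574 and 4665, and Cxcl2, at 10910 and 4972, faced receptors with 0 UMIs in NK-like cells.

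The young laser comparison asked what differs 3 days after laser in young mice. In Müller-glia-like cells Gfap, an intermediate filament raised in reactive glia, was 128-fold (54.2 to 395) higher and Lcn2, an acute-phase iron binder, 49.6-fold (32.2 to 80.6) higher, while Prss56 was 3.996-fold (2.91 to 5.60) and Adamts19 3.70-fold (2.51 to 5.65) lower. In rod-like cells Bcl3, an NF-kB cofactor, was 45.5-fold (21.7 to 115) and Zbtb7c 28.3-fold (18.8 to 44.7) higher, and Akr1c21 37.0-fold (6.39 to 1484) lower. RPE-like cells had H19, an imprinted non-coding RNA, 226-fold (40.0 to 9001) and Serpine3 25.6-fold (21.6 to 30.5) higher, with Mmp3, a matrix protease, 11.4-fold (6.91 to 20.2) and Fmo2 4.63-fold (2.09 to 12.1) lower. Cone-like cells had Fgf2, a survival factor, 5.72-fold (2.58 to 14.4) and Nr4a1 2.02-fold (1.55 to 2.64) higher and Zfp101 4.30-fold (1.92 to 11.3) lower. In endothelial-like cells Zbp1, a nucleic acid sensor, was 9.08-fold (6.44 to 13.2) higher and Cyp26b1, which degrades retinoic acid, 6.65-fold (5.87 to 7.56) lower. Fibroblast-like cells had Gzmd at least 39.2-fold and Lrrc15, a marker of activated fibroblasts, 35.6-fold (24.1 to 55.1) higher and Car3, a carbonic anhydrase, 5.57-fold (4.40 to 7.09) lower. Macrophage/monocyte-like cells had Mucl1 at least 11.3-fold and the acute-phase gene Saa3 at least 6.57-fold higher, and the lowest ratios were rod genes. In pericyte/smooth-muscle-like cells the leading higher genes were cell cycle genes under 0.1 of their level in an unnamed cluster, and Scgb1a1 was 20.2-fold (5.24 to 172) lower. With thinned cells the intervals of Mmp3 and Fmo2 in RPE-like and of Fgf2, Nr4a1 and Zfp101 in cone-like cells also spanned 0.

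Gene lists of the young laser comparison are given in the class of their subject. Müller gliosis genes were at 1.70 at percentile 100, with 14 of 16 measured members higher, 0 lower and 2 spanning 0, such as Timp1 at 6.36 and Serpina3n at 5.60. Cell cycle genes were at 1.58 at percentile 100, with 13 of 15 measured members higher, 0 lower and 2 spanning 0 in endothelial-like cells, such as Ccnb2 at 2.83, and at 1.29 at percentile 100 in fibroblast-like cells, such as Ccnb1 at 3.39. A small fibroblast-like cluster led by Timp1 and Cenpf, with Top2a and Cdk1 among its leading genes, held 11 cells of young control and 44 of young CNV. Disease-associated microglia genes were at 0.78 at percentile 100, with 13 of 16 measured members higher, 0 lower and 3 spanning 0 in macrophage/monocyte-like cells, such as Gpnmb at 5.03 and Spp1 at 4.69. The unnamed cluster led by Arg1 and Spp1 is not among these cells, although list members such as Gpnmb, Fabp5 and Trem2 also lead it. It held 1, 193, 36 and 114 cells of young control, young CNV, aged control and aged CNV. Values of this list here and below leave those cells out. Matrix genes were at 0.75 at percentile 100, with 17 of 20 measured members higher, 3 lower and 0 spanning 0 in fibroblast-like cells, such as Tnc at 2.65 and Postn at 2.03, and senescence genes at 0.46 at percentile 100, with Cdkn2b at 4.39 and Cdkn2a at 3.86. Leukocyte adhesion genes were at 0.24 at percentile 98.6 in endothelial-like cells, with Ackr1 at 1.41 and Selp at 0.81, or 0.19 at percentile 93.2, inside the random range, with cells thinned to 1000 UMIs. Cone-like cells had phototransduction genes at -0.30 at percentile 0, with 1 of 17 measured members higher, 15 lower and 1 spanning 0, with the rod gene Pde6b at -1.06. Of these members Gpnmb, Spp1, Ackr1, Pde6b and Ccnb1 stood under 0.1 of their level in another class or an unnamed cluster, so they are open to free RNA. Outside the class given, gliosis genes were above the random range in 8 of 12 other classes, such as 1.66 at percentile 100 in rod-like cells, disease-associated microglia genes in 12 of 13, matrix genes in 11 of 13 and cell cycle genes in 5 of 8. Phototransduction genes were below it in 12 of 12 and visual cycle genes in 7 of 13, with visual cycle genes above it in melanocyte-like cells. Gliosis genes were below it in corneal or lens epithelium-like cells and matrix genes in bipolar-like cells.

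Other lists in the same comparison lay inside the random range. They were NF-kB genes (-0.12 at percentile 33.9) and homeostatic microglia genes (-0.11 at percentile 46.3) in macrophage/monocyte-like cells and angiogenesis genes (-0.029 at percentile 43.0, with Aplnr at 2.01 and Pgf at 1.62) and hypoxia genes (0.094 at percentile 94.3) in endothelial-like cells. NF-kB genes were above the range in 5 and below it in 3 of 12 other classes. Inside it in their own class were also Müller homeostasis genes in Müller-glia-like cells (-0.099 at percentile 38.5), visual cycle genes (-0.042 at percentile 37.0) and oxidative stress genes (0.0067 at percentile 72.5) in RPE-like cells, and phototransduction genes in rod-like cells (-0.068 at percentile 53.4). Type I interferon genes were above the random range in 7 of 7 classes with medians of 0.73 to 2.83, such as Isg15 at 4.70 in Müller-glia-like cells, and interferon gamma response genes in 8 of 8. Over every class type I genes were above in 11 of 13 and below in corneal or lens epithelium-like cells, at -0.13 at percentile 0.375, and interferon gamma genes were above in 12 of 13. Complement genes were above in 7 of 8 classes and class I antigen presentation genes in 7 of 8, or 10 of 14 and 8 of 13 over every class. Immediate early genes were above in RPE-like, cone-like, Müller-glia-like and rod-like cells and below in the other 4 of 8 classes, or above in 4 and below in 8 of 14 over every class. The list called immediate early here also holds genes of tissue dissociation, such as the heat-shock genes Hspa1a and Dnajb1. With cells thinned to 1000 UMIs Fmo2 in RPE-like cells was at 0.57, interferon gamma genes were above in 5 of 5 classes with a value and complement genes in 4 of 5, and the hypoxia median was 0.35, above the random range. The largest clusters of rod-like and fibroblast-like cells differed between the 2 libraries, led by Glp2r against Edn2 in rods and by Pappa2 against Clec3b in fibroblasts. That of pericyte/smooth-muscle-like cells differed too, led by Myh11 in young control and by Abcc9 in young CNV.

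The aged laser comparison asked the same of aged mice. RPE-like cells had Serpina3n, a protease inhibitor of the acute phase, 177-fold (131 to 244) and Timp1, an inhibitor of matrix proteases, 86.3-fold (41.1 to 218) higher, with Sostdc1 3.03-fold (2.67 to 3.45) and Enpp2 2.76-fold (2.62 to 2.91) lower. Müller-glia-like cells had the chemokine gene Ccl21a 173-fold (30.7 to 6853) and Lcn2 23.5-fold (20.3 to 27.3) higher and Npsr1 4.35-fold (3.02 to 6.41) lower. Interferon-induced genes led in rod-like cells, with Ifit3 27.4-fold (16.0 to 51.0) and Oasl2 24.6-fold (12.5 to 55.2) higher and Cib4 4.67-fold (2.73 to 8.57) lower, and in T-like cells, with Ifit1 9.65-fold (4.61 to 23.3) higher and Alpk2 16.2-fold (4.19 to 138) lower. Cone-like cells had Lad1 16.9-fold (5.18 to 87.2) higher and Arr3, the cone arrestin, 2.66-fold (2.60 to 2.72) lower. Endothelial-like cells had the mitotic gene Birc5 at least 33.4-fold and the replication gene Uhrf1 at least 17.6-fold higher and Mmp16 4.34-fold (3.59 to 5.26) lower. Fibroblast-like cells had Bhmt at least 34.3-fold and Cxcl13, a B cell chemokine, 27.1-fold (21.6 to 34.3) higher and Dlk1 24.5-fold (10.1 to 77.3) lower. Macrophage/monocyte-like cells had Cxcl13 93.2-fold (55.4 to 171) and Ifit3 16.6-fold (11.0 to 26.3) higher, with the interferon-gamma-induced Cxcl9 36.1-fold (21.8 to 64.0) lower, and Cxcl13 leads their largest cluster in aged CNV. Pericyte/smooth-muscle-like cells had Stc1 62.1-fold (10.6 to 2510) higher and Pcsk1 4.24-fold (3.03 to 6.08) lower. Cfd, an adipocyte gene, was also among the leading genes of 4 classes but stayed under 0.1 of its level in an unnamed cluster led by Cfd, Car3 and Adipoq.

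Neutrophil-like cells of aged control and aged CNV came mostly from different clusters, led by Retnlg, S100a9 and S100a8 in the control and by Acod1, Il1r2 and Ccrl2 after laser. The leading differences, Ccl3 43.7-fold (20.1 to 119) higher and Stfa1 20.5-fold (12.8 to 34.0) lower, are leading genes of these clusters. NF-kB genes were at 2.18 at percentile 100, with 11 of 16 measured members higher, 2 lower and 3 spanning 0, and at 1.44 with the 3 members seen in 1 library alone set to their bound, with Il1a at least 6.09-fold higher. Granule genes were at -1.44 at percentile 0.0300, with 3 of 10 measured members higher, 6 lower and 1 spanning 0, with Mmp8 at -2.93 and Chil3 at 4.78. Maturation and ageing genes were at 0.38 at percentile 88.0, or 0.82 at percentile 98.3, above the random range, with cells thinned to 1000 UMIs, with Icam1 at 3.01, and extracellular trap genes at -0.41 at percentile 26.7, with Padi4 at -2.19 and Cybb, under 0.1 of its level in another class, at 1.84.

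Lists of the aged laser comparison were read in the same way. Müller gliosis genes were at 1.61 at percentile 100, with 17 of 18 measured members higher, 0 lower and 1 spanning 0, such as Bcl3 at 3.53 and Socs3 at 3.16. NF-kB genes in macrophage/monocyte-like cells were at 1.25 at percentile 100, with 16 of 19 measured members higher, 1 lower and 2 spanning 0, such as Cxcl1 at 4.92 and Ccl3 at 2.68. Cell cycle genes were at 6.14 at percentile 100 in endothelial-like cells, or 2.63 with 5 members seen in 1 library alone at their bound, and at 4.18 at percentile 100 in fibroblast-like cells, such as Top2a at 7.46. The fibroblast-like median was 0.19 at percentile 86.6, inside the random range, with cells thinned to 1000 UMIs. Top2a is also a leading gene of the fibroblast-like cluster led by Timp1 and Cenpf. That cluster held 0 cells of aged control and 16 of aged CNV. Whether the fibroblast-like cell cycle values follow this cluster was not tested. Disease-associated microglia genes were at 0.37 at percentile 99.7 in macrophage/monocyte-like cells, with Cd63 at 1.46 and Gpnmb at -1.28, and homeostatic microglia genes at 0.26 at percentile 95.3. These values leave out the unnamed cluster led by Arg1, Spp1 and Gpnmb, with 36 cells of aged control and 114 of aged CNV. Matrix genes in fibroblast-like cells were at 0.29 at percentile 99.95, with Col3a1 at 1.73 and Ccn2 at -1.16, and senescence genes at 0.073 at percentile 90.8. The largest fibroblast-like cluster differed between aged control and aged CNV, and Col3a1 is a leading gene of that of aged CNV. Endothelial-like cells had hypoxia genes at 0.41 at percentile 99.91, with Pgk1 at 1.44, and angiogenesis genes at -0.22 at percentile 4.90, or -0.31 at percentile 0.380, below the random range, with cells thinned to 1000 UMIs, with Aplnr at 2.82 and Esm1 at -1.65. Ccl3, Top2a and Gpnmb stood under 0.1 of their level in another class and are open to free RNA. In other classes gliosis genes were above the random range in 9 of 12, disease-associated microglia genes in 11 of 12, matrix genes in 9 of 10, NF-kB genes in 6 of 9 and cell cycle genes in 5 of 8. Matrix genes were below it in muscle-like cells.

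Visual cycle genes in RPE-like cells were at -0.39 at percentile 0.0200, with 2 of 12 measured members higher, 10 lower and 0 spanning 0, such as Rrh at -0.87 and Lrat at -0.78, and in other classes below the random range in 6 and above it in 2 of 12. Phototransduction genes in rod-like cells were at -0.33 at percentile 0.0450, with 2 of 17 measured members higher, 15 lower and 0 spanning 0, and in cone-like cells at -0.081 at percentile 12.1, or -0.24 at percentile 0.960, below the random range, with cells thinned to 1000 UMIs. Müller homeostasis genes were at -0.46 at percentile 0.195, with 1 of 11 measured members higher, 8 lower and 2 spanning 0, with Glul, which makes glutamine, at -1.13, or -0.34 at percentile 4.37, inside the random range, with cells thinned to 1000 UMIs. Oxidative stress genes in RPE-like cells were at 0.31 at percentile 99.88, or 0.060 at percentile 64.7, inside the random range, with cells thinned to 1000 UMIs, with Hmox1, under 0.1 of its level in an unnamed cluster, at 2.35. T-like cells had NK-type cytotoxic genes at -0.20 at percentile 4.94, maturation genes at -0.17 at percentile 10.3, cytokine genes at 0.075 at percentile 73.7 and inhibitory genes at -0.14 at percentile 13.8. Leukocyte adhesion genes in endothelial-like cells were at 0.27 at percentile 97.2, or 0.34 at percentile 98.8, above the random range, with cells thinned to 1000 UMIs. Among their members Selp was at 2.46. Type I interferon genes were above the random range in 10 of 10 classes with medians of 1.06 to 3.29, interferon gamma genes in 8 of 10, complement genes in 9 of 10 and class I genes in 8 of 10, or 5 of 5 classes with a value for complement and 5 of 8 for class I with cells thinned to 1000 UMIs. Over every class these 4 lists were above in 12 of 13, 9 of 12, 10 of 12 and 10 of 13. Immediate early genes were above in RPE-like, cone-like, Müller-glia-like and rod-like cells and in 0 classes below, or above in 5 and below in 1 of 13 over every class.

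**Figure D3:**
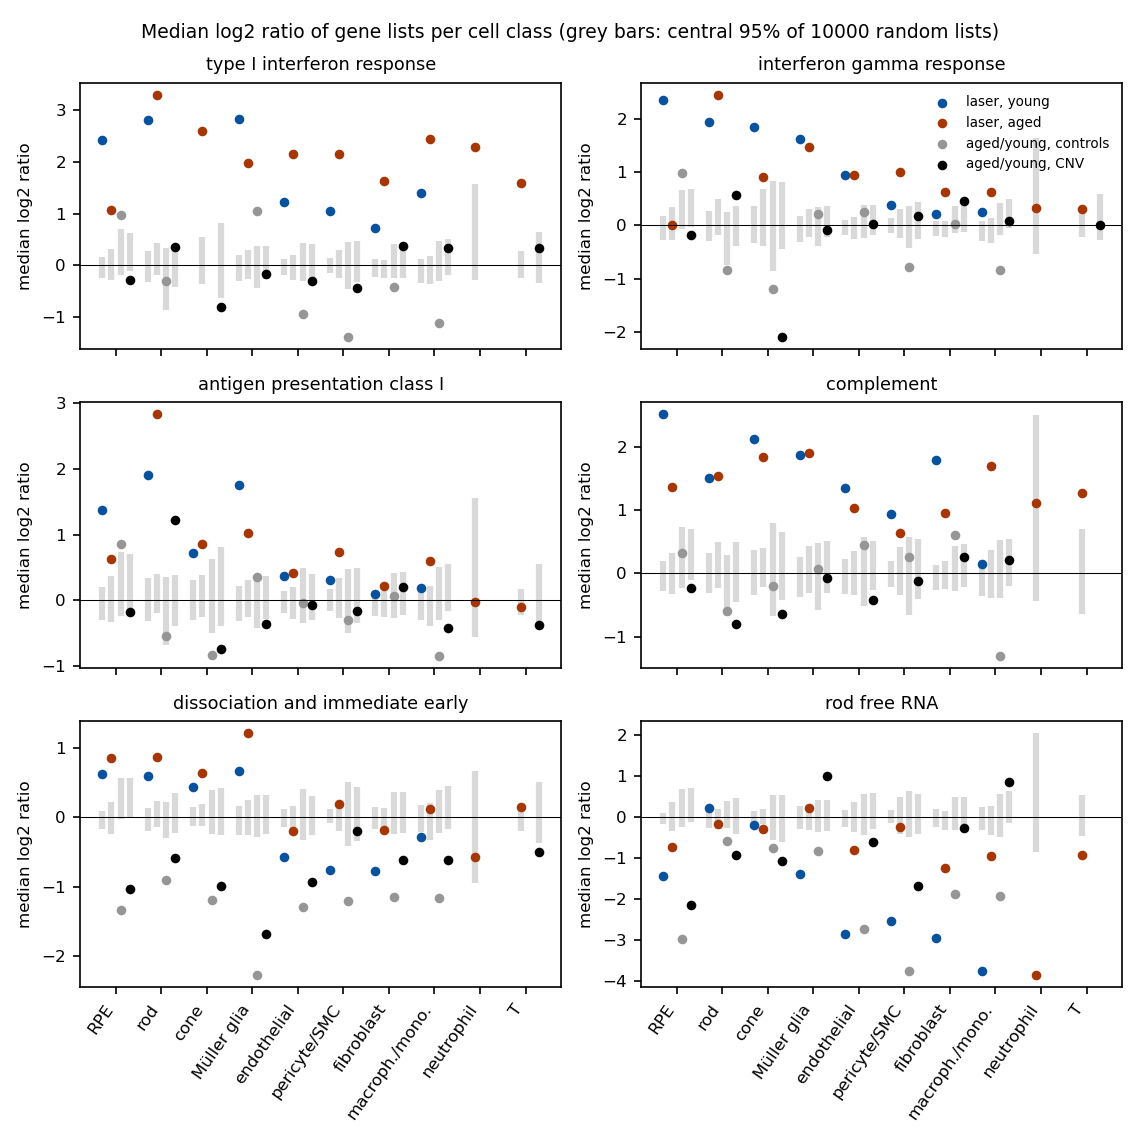
Median log2 ratio of gene lists (y axes) for the 10 cell classes described (x axes) in the 4 comparisons (point colours), with grey bars for the central 95% of 10000 matched random lists. Type I interferon medians of the laser comparisons lie above the grey bars in 7 of 7 of these classes in young and 10 of 10 in aged mice, and immediate early medians of the age comparisons lie below them in 8 of 8 classes without and 8 of 9 with lesions.

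The comparison of aged with young controls asked what differs with age before laser. Immediate early genes, which are induced within minutes of a stimulus, were below the random range in 8 of 8 classes with medians of -2.28 to -0.91, and in 10 of 10 over every class up to -0.83, such as Klf4, under 0.1 of its level in another class, at -6.41 and Ier2 at -3.75 in Müller-glia-like cells. As their list also holds tissue dissociation genes, among them heat-shock genes, age and handling of the suspensions cannot be told apart here. In rod-like cells Dpp10, an ion channel subunit, was 262-fold (221 to 311) higher and is a leading gene of the cluster that held most rod-like cells of the aged libraries, while the serotonin receptor Htr1f was 148-fold (26.4 to 5856) and Gulp1 13.8-fold (11.7 to 16.3) lower. Cone-like cells had Pcp4l1 17.7-fold (11.8 to 27.7) and Kcnc4 at least 10.1-fold higher and Htr1f 73.9-fold (19.2 to 629.5) lower. Müller-glia-like cells had A2m, a protease inhibitor, 89.1-fold (40.7 to 244) and Nxph1 60.2-fold (35.7 to 111) higher and Csmd2 82.7-fold (14.4 to 3307) lower. RPE-like cells had Bcan, a matrix proteoglycan, 29.8-fold (12.6 to 92.7) and Lars2 8.25-fold (7.66 to 8.88) higher and Ggt1 7.56-fold (5.76 to 10.1) and Mmp3 5.63-fold (4.39 to 7.29) lower. Endothelial-like cells had Slc6a2 26.5-fold (14.3 to 54.4) higher, and Steap4 24.3-fold (12.7 to 53.5) and Ndufa4l2 19.7-fold (10.9 to 39.8) lower, which are leading genes of a pericyte-like cluster. Fibroblast-like cells had the collagenase Mmp13 76.2-fold (38.3 to 178) higher and Gpha2 32.5-fold (24.2 to 44.6) lower. Macrophage/monocyte-like cells had Saa3 at least 273-fold and Alox15, a lipoxygenase, at least 19.97-fold higher and Ccn1 35.4-fold (16.0 to 97.8) lower, with Saa3 among the leading genes of their largest cluster in aged control. Pericyte/smooth-muscle-like cells had Pcsk1 12.6-fold (9.29 to 17.5) higher and Myoc 50.3-fold (26.4 to 110.2) lower. Myoc is a leading gene of a fibroblast-like cluster. The largest pericyte/smooth-muscle-like cluster, led by Myh11, held 39% of these cells in young control and 81.9% in aged control.

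Gene lists between controls were also not confined to the class of their subject. In other classes gliosis genes were above the random range in 4 of 9, such as 1.21 at percentile 100 in rod-like and 0.95 at percentile 99.94 in RPE-like cells, NF-kB genes were below it in 6 of 9, matrix genes in 7 of 9 and phototransduction genes in 8 of 8. Matrix genes were above it in muscle-like cells. NF-kB genes in macrophage/monocyte-like cells were at -1.503 at percentile 0, with 1 of 18 measured members higher, 14 lower and 3 spanning 0, such as Ccl3 at -3.93 and Ccl2 at -3.31. Homeostatic microglia genes in the same cells were at -1.04 at percentile 0, with 1 of 10 measured members higher, 9 lower and 0 spanning 0, such as Gpr34 at -1.65, and disease-associated microglia genes at -0.10 at percentile 8.85, with Gpnmb at 6.58 and Apoe at -1.33. Left out of these cells is the unnamed cluster led by Arg1, Spp1 and Gpnmb, with 1 cell of young control and 36 of aged control. Müller gliosis genes were at 1.05 at percentile 100, with 10 of 14 measured members higher, 4 lower and 0 spanning 0, such as Serpina3n at 4.78 and C4b at 3.67, and Müller homeostasis genes at -0.21 at percentile 5.16. Cell cycle genes were at -1.96 at percentile 0 in endothelial-like cells, or -1.79 with 3 members at their bound, and at -2.60 at percentile 0 in fibroblast-like cells, or -0.48 at percentile 4.46, inside the random range, with cells thinned to 1000 UMIs. The fibroblast-like cluster led by Timp1 and Cenpf, with Top2a and Cdk1, held 11 cells of young control and 0 of aged control. Phototransduction genes were at -0.45 at percentile 0.0700 in rod-like and -0.99 at percentile 0, with 1 of 17 measured members higher, 15 lower and 1 spanning 0 in cone-like cells, with Gngt1, also a member of the rod free RNA list, at -2.68. Gpr34 and Gpnmb stood under 0.1 of their level in another class and are open to free RNA. Hypoxia genes (-0.30 at percentile 2.82), angiogenesis genes (0.086 at percentile 50.5) and adhesion genes (0.28 at percentile 78.3) were read in endothelial-like cells, and matrix genes (-0.0016 at percentile 31.6) and senescence genes (0.13 at percentile 57.2, with Mmp3 at 2.495) in fibroblast-like cells. Visual cycle genes (0.39 at percentile 94.0, or 0.43 at percentile 98.4, above the random range, with cells thinned to 1000 UMIs) and oxidative stress genes (0.073 at percentile 40.4) were read in RPE-like cells, with visual cycle genes above the random range in 6 of 9 other classes. Type I interferon genes were above in RPE-like and Müller-glia-like cells and below in 4 of 7 classes, and with cells thinned to 1000 UMIs in 0 above and 3 below of 5. Interferon gamma genes were above in 1 and below in 4 of 8 classes, complement genes above in 1 and below in 1, and class I genes above in 1 and below in 2. With cells thinned to 1000 UMIs these 3 lists were above in 0 and below in 4 of 6, 2 of 3 and 1 of 6 classes with a value. Over every class these 4 lists were above in 2 of 8, 1 of 9, 1 of 9 and 1 of 9 and below in 4, 5, 1 and 3, bipolar-like cells adding the lower interferon gamma and class I medians of -1.06 at percentile 0.140 and -0.96 at percentile 0.545. The largest clusters of rod-like and macrophage/monocyte-like cells differed between the 2 libraries.

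The comparison of aged with young mice after laser asked what differs between the CNV libraries. Controls are not subtracted, so its values also hold differences present without laser and are not differences in the response. Dpp10 and Gulp1 in rod-like, Pcp4l1 in cone-like and Nxph1 in Müller-glia-like cells took the same direction between controls. Cxcl13 was 1115-fold (541 to 2776) and Saa3 29.8-fold (24.9 to 35.9) higher in macrophage/monocyte-like cells of aged CNV, both leading genes of their largest cluster there, and Mucl1 was at least 27.3-fold and Ccn1 14.3-fold (8.45 to 26.3) lower. RPE-like cells had Serpina3n 19.9-fold (17.0 to 23.6) higher, and H19 at least 36.0-fold and Tnfaip6, a leading gene of a fibroblast-like cluster, 57.9-fold (19.6 to 283) lower. Rod-like cells had Dpp10 64.3-fold (54.0 to 77.2) higher and Gulp1 14.1-fold (11.1 to 18.2) and Gngt1, a transducin subunit, 7.14-fold (6.80 to 7.49) lower. Cone-like cells had Pcp4l1 26.2-fold (13.7 to 57.6) higher and Igf2bp2 32.8-fold (10.4 to 166) lower, and Müller-glia-like cells had Nxph1 57.2-fold (24.4 to 177) and Ccl21a 100.4-fold (17.8 to 3986) higher and Htr1f 50.8-fold (8.31 to 2085) lower. Endothelial-like cells had Cyp26b1 12.5-fold (11.1 to 14.2) higher, and Higd1b 24.4-fold (12.3 to 56.9) lower, a leading gene of a pericyte-like cluster. Fibroblast-like cells had Adamdec1 91.9-fold (45.8 to 215) and Serpina3m 84.2-fold (40.0 to 212) higher and Gzmd at least 28.4-fold and Gzme at least 19.9-fold lower. Pericyte/smooth-muscle-like cells had Myh6, a cardiac myosin, at least 31.8-fold higher and the growth factor Ptn 75.7-fold (44.2 to 142) lower, a leading gene of a pericyte-like cluster with 130 cells in young CNV and 6 in aged CNV. T-like cells had Lypd2 at least 34.4-fold and Gzma 6.92-fold (5.68 to 8.46) lower.

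Matrix genes in fibroblast-like cells were at -0.67 at percentile 0, with 4 of 20 measured members higher, 15 lower and 1 spanning 0, such as Postn at -2.12 and Col1a1 at -1.81. In 11 of 11 other classes matrix genes were also below the random range. Müller gliosis genes were at 0.88 at percentile 100, with 11 of 17 measured members higher, 3 lower and 3 spanning 0, such as A2m at 2.53, with Socs3 at -1.44, and Müller homeostasis genes at -0.49 at percentile 0.740. In other classes gliosis genes were above in 5 of 12 and Müller homeostasis genes in 6 of 10, disease-associated microglia genes below in 7 and above in 1 of 12, NF-kB genes below in 9 of 12 and visual cycle genes above in 5 of 11. Homeostatic microglia genes in macrophage/monocyte-like cells were at -0.68 at percentile 0.0100, disease-associated microglia genes at -0.29 at percentile 0.440, with 5 of 16 measured members higher, 10 lower and 1 spanning 0, with Spp1 at -1.46, and NF-kB genes at -0.11 at percentile 3.78, or -0.54 with cells thinned to 1000 UMIs. These values leave out the unnamed cluster led by Arg1, Spp1 and Gpnmb, with 193 cells of young CNV and 114 of aged CNV. Endothelial-like cells had adhesion genes at 0.48 at percentile 97.4, such as Ackr1 at 2.80, or 0.25 under trimmed-mean scaling, angiogenesis genes at -0.067 at percentile 15.3, hypoxia genes at 0.31 at percentile 88.7 and cell cycle genes at 0.16 at percentile 55.9. Fibroblast-like cells had cell cycle genes at -0.38 at percentile 0.0600 and senescence genes at -0.099 at percentile 6.27. Their cluster led by Timp1 and Cenpf, with Top2a and Cdk1, held 44 cells of young CNV and 16 of aged CNV. RPE-like cells had visual cycle genes at 0.20 at percentile 72.5 and oxidative stress genes at 0.29 at percentile 78.5, and phototransduction genes were at -0.57 at percentile 0.0800 in rod-like and -0.89 at percentile 0 in cone-like cells. In T-like cells NK-type cytotoxic genes were at -0.17 at percentile 12.99, maturation genes at 0.054 at percentile 36.8, cytokine genes at -0.19 at percentile 13, with Ccl3 at -2.66, and inhibitory genes at 0.34 at percentile 66.7, with Tigit at 2.87 and Havcr2 at 2.17. Spp1 in macrophage/monocyte-like and Ccl3 in T-like cells stood under 0.1 of their level in another class and are open to free RNA. Immediate early genes were below the random range in 8 of 9 classes, with pericyte/smooth-muscle-like cells the exception at -0.20 at percentile 9.46, and in 11 of 13 over every class. Type I interferon genes were below in 4 of 9 classes and complement genes in 4 of 8, or 2 of 8 and 2 of 7 with cells thinned to 1000 UMIs, while interferon gamma genes were above in 2 and below in 2 of 9 and class I genes above in 1 and below in 3 of 9, or above in 2 and below in 1 of 8 and above in 1 and below in 2 of 7 with thinned cells. Over every class type I, complement, interferon gamma and class I genes were below in 5 of 13, 6 of 12, 5 of 13 and 4 of 13 and above in 0, 2, 2 and 1.

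Further lists outside the class they are described in were counted over all other classes with a value, above and below the random range. In the young laser comparison the classes above and below were 3 and 0 of 5 for homeostatic microglia, 3 and 2 of 12 for angiogenesis and 1 and 2 of 5 for adhesion genes. They were 1 and 2 of 13 for Müller homeostasis, 1 and 3 of 13 for hypoxia, 7 and 1 of 13 for senescence and 5 and 0 of 13 for oxidative stress genes. In the aged laser comparison the classes above and below were 0 and 1 of 4 for homeostatic microglia, 4 and 0 of 9 for angiogenesis, 3 and 0 of 4 for adhesion and 3 and 0 of 11 for Müller homeostasis genes. In that comparison they were 3 and 0 of 12 for hypoxia, 3 and 6 of 11 for phototransduction, 7 and 0 of 11 for senescence and 9 and 0 of 12 for oxidative stress genes. Neutrophil lists there had 1 and 0 of 2 for neutrophil granule, 5 and 0 of 8 for neutrophil maturation, and 2 and 0 of 5 for extracellular trap genes. NK-type lists had 0 and 0 of 1 for cytotoxic, 0 and 1 of 6 for NK maturation, 4 and 0 of 4 for NK cytokine and 1 and 0 of 4 for NK inhibitory genes. Between controls the classes above and below were 0 and 1 of 4 for homeostatic microglia, 2 and 2 of 9 for disease-associated microglia, 0 and 3 of 9 for angiogenesis, 1 and 0 of 2 for adhesion and 0 and 3 of 9 for Müller homeostasis genes. They were 0 and 3 of 9 for hypoxia, 0 and 1 of 5 for cell cycle, 0 and 2 of 9 for senescence and 0 and 4 of 9 for oxidative stress genes. Between CNV libraries the classes above and below were 0 and 3 of 7 for homeostatic microglia, 1 and 1 of 11 for angiogenesis, and 1 and 0 of 5 for adhesion genes. There were 4 and 1 of 12 for hypoxia, 3 and 5 of 10 for phototransduction and 2 and 2 of 10 for cell cycle genes. They were 0 and 7 of 12 for senescence and 0 and 3 of 12 for oxidative stress genes. NK-type lists there had 1 and 0 of 3 for cytotoxic, 0 and 0 of 7 for NK maturation, 0 and 2 of 7 for NK cytokine and 0 and 0 of 7 for NK inhibitory genes.

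The change of the laser difference between young and aged mice was read over 67 pairs of gene and class, with 64 distinct genes, named in either laser comparison and measured in both. Of these pairs 47 had the same direction with both intervals excluding 0, 7 opposite directions with both intervals excluding 0, and 13 an interval spanning 0. Mmp3 in RPE-like cells was -3.51 (-4.34 to -2.79) in young and 0.73 (0.15 to 1.29) in aged, and Dpp10 in rod-like cells 0.61 (0.26 to 0.97) in young and -1.41 (-1.47 to -1.35) in aged, on the log2 scale. Gfap in Müller-glia-like cells was 6.99 (5.76 to 8.63) in young and 2.69 (2.38 to 3.01) in aged, and Timp1 in RPE-like cells 3.21 (1.66 to 5.20) in young and 6.43 (5.36 to 7.77) in aged. With cells thinned to 1000 UMIs Gfap was at 3.48 (1.29 to 6.70) in young and 2.52 (1.27 to 4.05) in aged, overlapping intervals. Timp1 was then at 0.57 (-2.33 to 3.47) in young, spanning 0, and 4.54 (2.78 to 6.93) in aged. These differences between ages were not tested, because each group has 1 library. With cells thinned to 1000 UMIs 28 pairs had the same direction and 2 opposite directions. Of the 7 only Nkain3 in pericyte/smooth-muscle-like cells was among these 2, and the other 6 had an interval spanning 0.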

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

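The tests of erythroid-like cells, of the leukocyte denominator, of RPE-like, rod-like and Müller-glia-like cells as a group, of cone-like cells alone, of the direction of depth, and of handling were chosen only after the results were seen; the tests of cells picked by their own UMIs, of free RNA in vessel and stroma classes and in retina and RPE classes together, and of thinning were written before. Every difference between young and aged laser values below was not tested, because each group has 1 library.

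Neutrophil-like cells were 15.4 (9.60 to 26.1) times as frequent in aged CNV as in young CNV. Blood carried over would bring erythroid-like cells along, and these were less frequent in aged CNV, at a ratio of 0.264 (0.153 to 0.434). A change of the denominator through rod depletion left a ratio of 13.8 (8.60 to 23.4) among leukocytes other than microglia-like cells, and naming of clusters left 5.28 (3.70 to 7.69) with cells picked by their own UMIs. These values argue against each of the 3 as the whole cause. The leukocyte denominator cannot speak to tissue mix, since other tissue may bring its own leukocytes. Corneal or lens epithelium-like cells numbered 255 in young CNV and 387 in aged CNV, and cells of the unnamed cluster led by Cfd, Car3 and Adipoq 1 and 46. The age of the animals may account for the difference, which was not tested, and blood carried over, tissue mix and chance variation between animals stay open.

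Type I interferon genes were above the random range in 17 of 17 pairs of laser comparison and class among the 10 classes described, and in 23 of 26 over every class, where 1 pair was below it. Were their level in a CNV library free RNA of macrophage/monocyte-like cells, interferon genes would stand to those cells as macrophage markers do. Their lower quartile instead lay above the upper quartile of the markers in 6 of 6 pairs of vessel or stroma class and CNV library. In retina and RPE classes this held in 6 of 8 pairs, namely 6 of 6 in RPE-like, rod-like and Müller-glia-like cells and 0 of 2 in cone-like cells, where the lower quartiles were -5.38 and -6.63 against upper quartiles of -5.12 and -6.41 and a source in free RNA cannot be told apart. A difference in depth is argued against by 15 of 15 pairs with a value that stayed above the random range with cells thinned to 1000 UMIs. The comparison with macrophage markers cannot speak to free RNA from other classes. It used levels in the CNV libraries alone, so it cannot tell where the increase over control came from. Interferon genes that a class already expressed before laser would pass it either way. In endothelial-like cells the interferon genes stood near their macrophage/monocyte-like level, at a median log2 of 0.027 in young CNV and -0.49 in aged CNV. A response of the tissue to laser is a candidate explanation in the classes other than cone-like cells, as a hypothesis found on the same data and not settled by this comparison. Free RNA as a source of the increase, from macrophage/monocyte-like cells or other classes, and handling of each library stay open.

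Immediate early genes were below the random range in 16 of 17 pairs of age comparison and class among the 10 classes described, and in 21 of 23 over every class, the exception among the 17 being pericyte/smooth-muscle-like cells after laser. With cells thinned to 1000 UMIs 14 of 16 stayed below the random range, short of the 9 in 10 set beforehand. Depth in one direction is argued against by the aged library being the deeper one in 6 of the 16 pairs and the shallower one in the others. Handling of the suspensions would give the same 16 of 17 pairs as age, so handling and age cannot be told apart. Both stay open.

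Shares that moved opposite ways with laser in young and aged mice were the following, as CNV to control ratios. NK-like cells stood at 2.45 in young and 0.493 in aged mice and amacrine-like cells at 0.701 (0.0586 to 6.12) and 1.36 (0.949 to 1.96), all 4 intervals spanning 1. T-like cells stood at 2.19 and 0.962, endothelial-like cells at 1.51 and 0.953, and muscle-like cells at 1.47 (1.14 to 1.89) and 0.800 (0.560 to 1.14), the aged interval of each spanning 1. Pericyte/smooth-muscle-like cells stood at 1.001 (0.883 to 1.14) and 0.770 (0.631 to 0.940), the young interval spanning 1. Erythroid-like cells stood at 1.51 (1.11 to 2.08) and 0.455 (0.247 to 0.815), neither interval spanning 1. With rod-like cells left out of the denominator, a setting added after the results were seen, the young ratio was 1.42 (0.864 to 2.39) for T-like, 0.981 (0.882 to 1.09) for endothelial-like, 0.952 (0.741 to 1.23) for muscle-like, 0.649 (0.573 to 0.736) for pericyte/smooth-muscle-like and 0.980 (0.717 to 1.35) for erythroid-like cells, so the last 4 no longer took opposite directions.

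In the classes where each list is described, these list medians took opposite signs, as log2 ratios in young and then aged mice. Immediate early genes were at -0.28 at percentile 0.340 and 0.13 at percentile 92.7 in macrophage/monocyte-like cells and at -0.76 at percentile 0 and 0.19 at percentile 96.9 in pericyte/smooth-muscle-like cells. In macrophage/monocyte-like cells homeostatic microglia genes were at -0.11 and 0.26 and NF-kB genes at -0.12 and 1.25. The rod free RNA list was at -1.39 at percentile 0 and 0.23 at percentile 95.4 in Müller-glia-like cells and at 0.21 at percentile 95.9 and -0.18 at percentile 12.95 in rod-like cells. In other classes bipolar-like cells had rod free RNA, phototransduction, matrix and NF-kB genes below the random range in young and above it in aged mice, as had muscle-like cells for visual cycle and phototransduction genes, with matrix genes the other way round in the latter.

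Named genes with opposite signs are given as log2 ratios with intervals. Of the 7 with both intervals excluding 0, 1 stayed so with cells thinned to 1000 UMIs, namely Nkain3 in pericyte/smooth-muscle-like cells, and Cyp26b1 in endothelial-like cells joined it. In RPE-like cells Fmo2 was -2.21 (-3.59 to -1.07) in young and 1.06 (-0.024 to 2.09) in aged, the latter spanning 0, with the young value at 0.57 (-3.21 to 4.36) on 4 UMIs with thinned cells, and Mmp3 -3.51 (-4.34 to -2.79) in young and 0.73 (0.15 to 1.29) in aged. In cone-like cells Mef2c was -1.11 (-1.41 to -0.82) in young and 0.16 (0.072 to 0.25) in aged, Zc3h6 -1.37 (-1.90 to -0.86) in young and 0.37 (0.16 to 0.58) in aged and Zfp101 -2.10 (-3.50 to -0.94) in young and 0.022 (-0.50 to 0.53) in aged, the last aged interval spanning 0. In endothelial-like cells Cyp26b1 was -2.73 (-2.92 to -2.55) in young and 0.062 (-0.054 to 0.18) in aged, the latter spanning 0. In macrophage/monocyte-like cells Cxcl9 was 0.24 (-0.60 to 1.20) in young and -5.17 (-6.00 to -4.45) in aged, the former spanning 0. With thinned cells Cxcl9 was negative at both ages, at -0.56 (-2.885 to 2.71) in young and -4.89 (-8.03 to -2.85) in aged. Prg4 in the same cells was at 0.086 in young, a value against 3 counts for a library with 0 UMIs whose interval limit was -0.34, and at -4.04 (-5.31 to -2.96) in aged mice. Saa3 was at 2.72 in young, a value against 3 counts for a library with 0 UMIs whose interval limit was 2.40, and at -0.48 (-0.60 to -0.35) in aged mice. In Müller-glia-like cells Prss56 was -1.998 (-2.49 to -1.54) in young and 0.17 (-0.10 to 0.44) in aged, the latter spanning 0. With thinned cells Prss56 took the same sign at both ages, at -0.68 (-1.75 to 0.28) in young and -0.72 (-1.62 to 0.15) in aged. In pericyte/smooth-muscle-like cells Erbb4 was 1.04 (0.49 to 1.61) in young and -5.22 (-10.55 to -2.69) in aged, Pcsk1 0.49 (-0.058 to 1.04) in young and -2.08 (-2.60 to -1.60) in aged, the young interval spanning 0, and Nkain3 0.64 (0.40 to 0.89) in young and -2.53 in aged mice, a value against 3 counts for a library with 0 UMIs whose interval limit was -2.12. In rod-like cells Dpp10 was 0.61 (0.26 to 0.97) in young and -1.41 (-1.47 to -1.35) in aged.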

How the results depend on the processing

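With 1 library per group and no paired animals in the labels, no paired analysis was possible and no replicate could be left out. The denominator without rod-like cells, naming without the score margin, unnamed clusters as sources of free RNA and counts over every class were chosen only after the results were seen. Of 68 alternative values of NK-like and neutrophil-like shares 58 stayed within their interval, of 301 list medians 285 kept their sign and their side of the random range or stayed inside it, and of 1038 named gene values in the 10 classes 857 stayed within their interval, 178 moved beyond it in the same direction and 3 reversed. Trimmed-mean scaling left 197 of 210 named gene values within their interval, median-of-ratios scaling 196, classes from resolution 2.0 209, kept doublets 192 of 209, and thinning to 1000 UMIs 63 of 199. Genes with 1 library at 0 and the other at or under 3 UMIs, 11 under thinning and 1 with doublets kept, gave no value. The filter at 200 genes and 25% removed 0 cells, so leaving it out is void, and clustering each library alone gave no NK-like cluster in 3 libraries and no neutrophil-like cluster in young control. The cause was not tested.

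With leukocytes other than microglia-like cells as the denominator, larger by construction, NK-like cells were 2.11%, 1.05%, 1.57% and 0.381% and neutrophil-like cells 1.06%, 1.42%, 6.28% and 19.6% in young control, young CNV, aged control and aged CNV. Picked by the cell's own UMIs, neutrophil-like cells were 0.378% in young CNV and 1.998% in aged CNV.

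Reversed log2 ratios in the young laser comparison were Fmo2 in RPE-like cells at 0.57 and Klhl1 in cone-like cells at -0.65 with thinned cells, and Myl10 in pericyte/smooth-muscle-like cells at 0.042 with doublets kept. With thinned cells list medians that came to lie inside the random range were -0.34 for Müller homeostasis, 0.19 for fibroblast cell cycle and 0.060 for RPE oxidative stress genes in the aged laser comparison, 0.19 for adhesion genes in the young one and -0.48 for fibroblast cell cycle genes between controls. Those that came to lie outside it were 0.82 for neutrophil maturation, -0.31 for angiogenesis, 0.34 for adhesion and -0.24 for cone phototransduction genes in the aged laser comparison, 0.35 for hypoxia genes in the young one, 0.43 for visual cycle genes between controls and -0.54 for macrophage NF-kB genes between CNV libraries. Adhesion genes in the aged laser comparison were at 0.27 both with members of at least 5 UMIs and with 20 bins, and visual cycle genes between controls at 0.39 with 20 bins, outside the range with an unchanged median. Adhesion genes between CNV libraries were at 0.25 under trimmed-mean scaling, outside it.

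With thinned cells and fewer classes with enough members, lists lay above the random range as follows. Interferon gamma genes were above in 5 classes in the young laser comparison and 0 between controls, type I interferon genes in 0 between controls, complement genes in 4 and 5 in the young and aged laser comparisons, 0 between controls and 1 between CNV libraries, class I genes in 5 in the aged laser comparison and 0 between controls, and rod free RNA in 1 in the young laser comparison and 0 between CNV libraries. Below it were interferon gamma genes in 1 and type I genes in 2 classes between CNV libraries, complement genes in 2 between controls and 2 between CNV libraries, class I genes in 1 between controls, and rod free RNA in 3 in the aged laser comparison and 3 between CNV libraries. With members of at least 5 UMIs, interferon gamma genes were above in 1 class between CNV libraries, and complement genes above in 2 and below in 2 between controls. Over every class type I genes were above in 11 and below in 1, class I genes below in 1, immediate early genes below in 8 and rod free RNA below in 13 in the young laser comparison, immediate early genes below in 1 and rod free RNA above in 2 in the aged one, and interferon gamma genes below in 5 and complement genes above in 2 between CNV libraries. Thinning left 28 gene and class pairs with the same direction in both laser comparisons and 2 with opposite directions.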

Other observations

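Cell classes outside the series' question also differed. Bipolar-like cells, the interneurons between photoreceptors and ganglion cells, were 0.773%, 1.46%, 7.51% and 18.6% of cells in young control, young CNV, aged control and aged CNV, with an aged to young ratio of 9.72 (7.71 to 12.4) in controls, or 5.71 (4.53 to 7.27) over cells other than rod-like, beside rod-like shares of 52.3% and 18.8%. Amacrine-like cells numbered 3, 2, 52 and 82. B/plasma-like cells, which make antibodies, had an aged to young ratio of 3.73 (1.87 to 7.84) in controls, or 2.19 (1.10 to 4.60) over cells other than rod-like, and 4.36 (2.34 to 8.62) after laser, and in aged CNV most came from a cluster led by Igkc, Mzb1 and Ighm, in the other libraries from a cluster led by Ighd, Pax5 and Cd79a. Corneal or lens epithelium-like cells numbered 246, 255, 30 and 387, an aged laser ratio of 11.1 (7.66 to 16.7). Melanocyte-like cells numbered 157, 201, 11 and 29, and mast-cell-like cells 2, 13, 12 and 15.

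Some genes differed with age in several classes. Htr1f was lower in aged control than in young control in rod-like, cone-like, Müller-glia-like and fibroblast-like cells, the latter 2 at 33.8-fold (8.98 to 285) and 58.1-fold (15.9 to 483). Apba2 was higher in aged control in fibroblast-like and pericyte/smooth-muscle-like cells, at 75.6-fold (34.2 to 208) and 43.8-fold (14.2 to 219.6), under 0.1 of its level in an unnamed cluster. In endothelial-like cells of aged control the class I genes took opposite directions, with H2-Q7 at 1.74, H2-T23 at -1.48 and B2m at -0.67. In RPE-like cells the class II genes H2-Ab1 and Cd74, which present antigen to helper T cells, were higher after laser in young mice, at 3.38 and 3.05, and lower in aged than in young CNV, at -3.85 and -3.85. Both stood under 0.1 of their level in another class and are open to free RNA.

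Unnamed clusters held cells of note. A cluster led by Arg1, Spp1, Mmp12, Gpnmb and Apoc2, whose score lay within the margin of macrophage/monocyte-like and platelet-like, held 1, 193, 36 and 114 cells of young control, young CNV, aged control and aged CNV. A cluster led by Cfd, Car3, Adipoq, Retn and Cidec, genes of adipocytes, held 0, 1, 0 and 46. A cluster led by Hist1h1b, Top2a and Mki67, genes of dividing cells, held 10, 52, 6 and 14. A cluster of bipolar-like or amacrine-like score led by Neto1, Nxph1 and Lrp1b held 219, 52, 48 and 44, a cluster led by Crhbp, Optc, Pld5, Folr1 and Slc26a4 held 23, 44, 1 and 6, and a cluster led by Lilra5, Cd86, Cd83 and Ccl4 held 73, 88, 26 and 43.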
